A study of Homo sapiens with 16 samples.

How the data were processed

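Poly(A)-selected RNA of the human glioblastoma cell line U-251 MG was sequenced as read pairs on an Illumina NextSeq instrument. Cells had been treated for 48 h, from 24 h after seeding, with DMSO, simvastatin at 0.06 µM, irinotecan at 0.6 µM or both drugs together. Each of the 4 groups held 4 libraries. In each group 1 library had no replicate number in its title, and it was called replicate 4. The labels do not say whether the libraries of a group came from separate cultures, so a p-value may measure technical spread only.

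The deposited table holds counts, whole numbers per gene for 58243 Ensembl gene IDs and 16 libraries, which the authors had not normalised. By the submitters' processing notes, reads were checked with FastQC and aligned with STAR 2.7.1 to GRCh38, and DESeq2 was also used. The annotation release, the counting step and the strand setting are not given in the sources used here. Counts of genes that overlap on opposite strands, or that share sequence with paralogs, therefore carry an uncertainty that could not be measured. Gene coordinates came from GENCODE 29 on GRCh38, which held 57980 of the gene IDs. Library totals ran from 24159673 to 32318888 counts. Libraries of the same group were checked for duplicates: the chi-squared statistic per degree of freedom of each pair, near 1 for a library counted again, was 2.58 to 14.8.

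Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by filterByExpr with the groups as design, a minimum count of 10 and a minimum total count of 15, which left 16647 genes. Libraries were scaled by TMM factors. Quasi-likelihood models with robust dispersions were fitted to all 16 libraries with 1 term per group, and 6 contrasts were tested by two-sided F tests. These were simvastatin against DMSO, irinotecan against DMSO, the combination against DMSO, the combination against each drug, and the interaction, which is the departure of the combination from the sum of the single-drug effects on the log2 scale. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Errors of log2 fold changes are standard errors from the size of the change and its F statistic. The common biological coefficient of variation was 5.25%. Levels of single genes are given in CPM from the cpm function of edgeR, with TMM-scaled library sizes. Summed levels of gene lists are in CPM of the library totals, without TMM factors. Comparisons of single values between groups used two-sided exact permutation tests.

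Gene lists with 812 entries were written before the data were examined, as were the groups, the contrasts, the tests, the alternatives and the rule for named genes. Of the entries, 809 matched the count table. There were 32 lists with at least 3 tested genes, which gave 192 tests over the 6 contrasts. Lists were tested with camera at a preset correlation of 0.01, two-sided and adjusted over all lists and contrasts. The same test with an estimated correlation, and fry, were run beside it. The numbers of called list members are given over all genes tested and adjusted over the list alone, and where both are equal they are said to hold by either adjustment.

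The named genes followed a rule in 4 parts. The first took, per comparison, the 10 called genes with the highest and the 10 with the lowest log2 fold change among those with a mean log2 CPM of at least 1 and a symbol that is not a clone name. The second took up to 4 members with the smallest p of each list described. The third took TOP1, TGFB1, TGFB2, TGFBR1, TGFBR2, SMAD3, SMAD7, CTGF (CCN2), CDKN1A, MKI67 and 3 genes whose results are left out, in every comparison. The fourth took all genes called in the interaction if there were 10 or fewer. Results of some further genes that the rule takes are left out. A gene named in 1 comparison could be given in the others.

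Overlaps of calls between contrasts were set against the product of their shares of all genes, against 20 simulations of unchanged groups, and against splits of the DMSO libraries into separate controls for each drug. The tests were tried on simulated data in which 200 of 16647 genes were changed. For simvastatin against DMSO, edgeR recovered 50% of genes changed by 0.3 log2 units, 72% at 0.5, 80% at 1 and 98% at 2, and 4.46% of calls were false. For the interaction it recovered 44%, 46%, 80% and 90%, and 6.47% of calls were false. Alternatives were DESeq2 1.42.0, median-ratio size factors, no filter on low counts, a stricter threshold, a minimum fold change, models with the replicate number as a block, models of the 12 numbered libraries or of the compared groups alone, and leaving out each library in turn. Scaling by library sizes alone was added after the data had been seen. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9. No library was left out.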

Results

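Poly(A) RNA was sequenced from U-251 MG, an established human glioblastoma cell line, after 48 h with vehicle (DMSO), simvastatin at 0.06 µM, irinotecan at 0.6 µM or both drugs, called the combination. Simvastatin is a statin, a drug that blocks the synthesis of cholesterol. Irinotecan is a prodrug of a topoisomerase I inhibitor, which leaves breaks in replicating DNA. The series was made to find the pathways and genes that these drugs affect alone and together, and its title names TGF-β. Each group held 4 libraries. Their total counts were 24478638 to 31932971 with DMSO, 24669799 to 29756711 with simvastatin, 24375152 to 32318888 with irinotecan and 24159673 to 27502415 with the combination. The share of counts from mitochondrially encoded genes was 2.37% to 4.58% per library, and it did not differ between groups past an exact permutation test (lowest p = 0.0857, combination against irinotecan). On the first principal component, with 25.9% of the variance, the 8 libraries with irinotecan lay apart from the 8 without it. The second held 11.0%.

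Of 16647 genes tested with edgeR, simvastatin alone changed 999, irinotecan alone 4015 and the combination 4677, all against DMSO. The combination differed from irinotecan alone in 989 genes and from simvastatin alone in 4259. Most changes were small: of the genes called, the median absolute log2 fold change was 0.24 with simvastatin, 0.28 with irinotecan and 0.28 with the combination. Over all genes tested, the libraries of the groups compared did not overlap in 10.0% to 26.2% of genes in these 5 comparisons, where chance gives 2.86%.

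**Figure D1:**
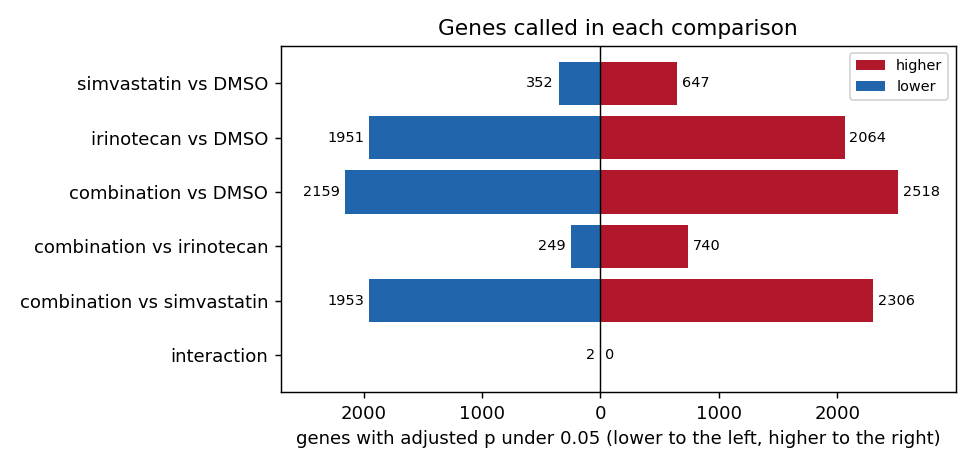
Number of genes with adjusted p under 0.05 in each comparison (n = 4 libraries per group), with lower genes drawn to the left and higher genes to the right of 0. Comparisons that differ by irinotecan called 4015 to 4677 genes, those that differ by simvastatin 989 and 999, and the interaction 2.

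Simvastatin against DMSO asked which transcripts respond to the statin alone. CXCL8, which encodes the neutrophil chemokine interleukin-8, rose from 1.05 ± 0.31 CPM to 34.2 ± 8.1 CPM (SD, n = 4), a fold of 32.6 (ENSG00000169429, GRCh38 chromosome 4, 73740506 to 73743716, adjusted p = 1.81e-09). INHBE, a gene for an inhibin beta subunit that responds to cell stress, rose from 1.45 ± 0.24 to 9.66 ± 1.94 CPM (ENSG00000139269, chromosome 12, 57452323 to 57459280, adjusted p = 4.43e-13). Log2 fold changes, with their standard errors, were 1.24 ± 0.08 for CHAC1, which degrades glutathione, 1.21 ± 0.10 for the stress cytokine GDF15, 1.00 ± 0.05 for the secreted glycoprotein STC2 and 0.99 ± 0.08 for CTH, which makes cysteine. Of the 999 genes called, 647 were higher and 352 lower, and with 1 library left out the lower genes were 195 (without simvastatin replicate 4) to 580 (without simvastatin replicate 3). At least 2-fold changes were seen in 31 of the higher and 5 of the lower genes, and HHIPL1 (-0.66 ± 0.16) and the serotonin receptor gene HTR1D (-0.62 ± 0.15) were among the lowest (here and below, of called genes with a mean log2 CPM of at least 1 and a symbol that is not a clone name).

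Lists of stress genes rose with simvastatin. Of 26 genes of the integrated stress and unfolded protein response, 19 rose and none fell (21 and 0 adjusted over the list alone), with a median log2 fold change of 0.37 (camera adjusted p = 4.15e-57, and adjusted p = 0.000669 with an estimated correlation). They included HERPUD1 (0.72 ± 0.05), a protein of endoplasmic reticulum degradation, the mTORC1 inhibitor gene DDIT4 (0.76 ± 0.05) and SESN2 (0.81 ± 0.06), which encodes another brake on mTORC1. Of 24 hypoxia and glycolysis genes 13 rose (20 adjusted over the list alone, camera adjusted p = 3.22e-26, adjusted p = 0.0233 with an estimated correlation), among them the prolyl hydroxylase gene P4HA2 (0.47), the mitophagy receptor BNIP3 (0.44) and the glycolytic enzyme PGK1 (0.28). In the list of inflammatory and secretory genes 10 of 23 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 1.38e-21, adjusted p = 0.000563 with an estimated correlation). Besides CXCL8 and GDF15 these were led by the cytokine genes IL11 (0.73) and LIF (0.50).

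Sterol genes rose in part. Of 25 SREBP2 targets 5 rose (8 adjusted over the list alone), led by HMGCS1, which makes HMG-CoA, from 131 ± 8 to 174 ± 14 CPM, and by MSMO1 and SQLE, enzymes later in the pathway. The list passed camera (adjusted p = 4.94e-07) but not with an estimated correlation (adjusted p = 0.149). Of 16 NRF2 targets 4 rose, by either adjustment, among them the cystine transporter gene SLC7A11 (0.60) and TXNRD1 (0.26); camera gave an adjusted p = 2.79e-05, and adjusted p = 0.0807 with an estimated correlation. Some cell cycle genes fell by small amounts. In the G2/M and mitosis list 11 of 34 genes fell (26 adjusted over the list alone), with KIF20A at -0.18, and in the replication and E2F list 8 of 36 (17 adjusted over the list alone), with E2F2 at -0.28. Both passed camera, with adjusted p = 3.11e-12 and 6.07e-07, and each had an adjusted p = 0.0507 with an estimated correlation. TOP1, the target of irinotecan, had a log2 fold change of 0.03 and the proliferation marker MKI67 -0.22, and neither was called. Without simvastatin replicate 4 the number of genes called was 664.

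Irinotecan against DMSO asked for the response to the topoisomerase I inhibitor alone. GFAP, the astrocyte intermediate filament gene, fell from 203 ± 10 to 94.7 ± 3.2 CPM (SD, n = 4, ENSG00000131095, chromosome 17, 44903161 to 44916937, adjusted p = 2.03e-18). CDKN1A, the p53-driven gene for the cell cycle inhibitor p21, rose from 51.5 ± 1.2 to 77.6 ± 1.0 CPM (ENSG00000124762, chromosome 6, 36676460 to 36687339, adjusted p = 6.19e-12). Among the highest log2 fold changes were CXCL8 (2.09 ± 0.29), the phospholipase gene LIPH (1.67 ± 0.13), GDF15 (1.45 ± 0.10), the apolipoprotein gene APOE (1.38 ± 0.16) and the neurotrophin receptor gene NGFR (1.33 ± 0.08). Among the lowest were the potassium channel partner KCNIP1 (-1.50 ± 0.11), PAPPA (-1.31 ± 0.08), a protease for insulin-like growth factor binding proteins, and the hypoxia-induced carbonic anhydrase gene CA9 (-1.23 ± 0.09). Of the 4015 genes called, 2064 were higher and 1951 lower.

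Lists of hypoxia and of sterol synthesis fell. Of 24 hypoxia and glycolysis genes 18 fell and none rose (20 and 1 adjusted over the list alone), with a median of -0.41 (camera adjusted p = 1.31e-33, adjusted p = 0.0103 with an estimated correlation), including PGK1 (-0.64), BNIP3 (-0.68) and ENO1 (-0.55). VEGFA, the angiogenic growth factor gene, fell from 509 ± 28 to 295 ± 22 CPM. Of 25 SREBP2 targets 17 fell and 1 rose (17 and 2 adjusted over the list alone, camera adjusted p = 2.08e-16, adjusted p = 0.0321 with an estimated correlation). HMGCS1 fell from 131 ± 8 to 70.0 ± 1.4 CPM (ENSG00000112972, chromosome 5, 43289395 to 43313512), and INSIG1, a feedback regulator of SREBP, fell as well (-0.64). Of 13 SREBP1 targets 8 fell (9 adjusted over the list alone), led by SCD (-0.72), which desaturates fatty acids; camera gave an adjusted p = 7.26e-10, and adjusted p = 0.0507 with an estimated correlation. Of 16 proneural and glial stem cell genes 8 fell, by either adjustment, with the brain fatty acid binding protein gene FABP7 at -0.70 and the transcription factor SOX9 at -0.44 (camera adjusted p = 4.63e-07, adjusted p = 0.00269 with an estimated correlation).

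Antigen presentation, p53 and epithelial genes rose with irinotecan. Of 13 antigen presentation genes 10 rose (11 adjusted over the list alone), among them B2M (0.34), the light chain of HLA class I, and HLA-E (0.36) (camera adjusted p = 6.92e-09, adjusted p = 0.0304 with an estimated correlation). Of 29 interferon response genes 20 rose and none fell (23 and 0 adjusted over the list alone), with a median of 0.45 and IFIT3, an antiviral gene, at 0.80; camera gave an adjusted p = 2.07e-09, and adjusted p = 0.158 with an estimated correlation. Of 29 p53 targets 10 rose and 1 fell (12 and 1 adjusted over the list alone, camera adjusted p = 0.00106, adjusted p = 0.0385 with an estimated correlation), with SESN2 (0.53), the ferredoxin reductase gene FDXR (0.37) and the death receptor gene TNFRSF10B (0.22) beside CDKN1A. Of 29 apoptosis regulators 10 rose and 1 fell (11 and 1 adjusted over the list alone, camera adjusted p = 0.00692, adjusted p = 0.0661 with an estimated correlation), including the BH3-only genes PMAIP1 (0.29) and BIK (0.96). Of 4 epithelial markers 3 rose, by either adjustment, with KRT8 at 0.56 ± 0.04 and CLDN4 at 0.67 ± 0.08 (camera adjusted p = 0.000153, adjusted p = 0.0447 with an estimated correlation). The summed level of the epithelial markers was 428 ± 22 CPM with DMSO and 623 ± 29 CPM with irinotecan (SD, n = 4). HLA and keratin genes share sequence with paralogs, and KRT8 overlaps KRT18 on the opposite strand.

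Replication and repair genes went both ways. Of 36 replication and E2F genes 15 rose and 11 fell (16 and 13 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.899). The helicase genes MCM6 (-0.50) and MCM5 (-0.42) fell, while RRM2 (0.32), a subunit of ribonucleotide reductase, and the licensing factor CDT1 (0.49) rose. Of 34 G2/M and mitosis genes 11 rose and 5 fell (14 and 6 adjusted over the list alone, camera adjusted p = 0.34), with CDK1 at 0.37 and CENPE, a centromere motor, at -0.40. Of 34 DNA damage and repair genes 11 rose and 4 fell (15 and 4 adjusted over the list alone, camera adjusted p = 0.0333, adjusted p = 0.223 with an estimated correlation), with the exonuclease gene EXO1 at 0.43 and the helicase gene BLM at 0.40. TOP1 itself had a log2 fold change of 0.09 ± 0.04 (adjusted p = 0.0797) and MKI67 one of -0.17. Among the other lists past camera, the integrated stress list had 4 genes higher and 13 lower by either adjustment (adjusted p = 0.00745, and adjusted p = 0.382 with an estimated correlation). The YAP and TEAD target list had 2 higher and 12 lower (4 and 13 adjusted over the list alone), led by AMOTL2 at -0.66 (adjusted p = 3.98e-06, and adjusted p = 0.0577 with an estimated correlation). The mesenchymal glioblastoma list tested as lower at a positive median of 0.04, with 8 genes higher and 9 lower (9 and 9 adjusted over the list alone, adjusted p = 0.0309, and adjusted p = 0.247 with an estimated correlation).

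The combination against DMSO asked for the response to both drugs together. CXCL8 rose to 26.0 ± 1.9 CPM and INHBE to 9.56 ± 1.56 CPM (SD, n = 4), with log2 fold changes of 4.63 ± 0.23 and 2.71 ± 0.15 (adjusted p = 1.06e-09 and 6.05e-14). GDF15 rose from 9.04 ± 0.95 to 34.9 ± 0.8 CPM, KCNK6, a potassium channel gene, by 2.06 ± 0.17 and HBEGF, a ligand of the EGF receptor, by 1.53 ± 0.11 on the log2 scale. GFAP fell to 92.1 ± 3.9 CPM, and the zinc finger gene ZNF423 (-1.37 ± 0.09), the semaphorin gene SEMA5B (-1.31 ± 0.14) and the semaphorin receptor gene PLXNA4 (-1.28 ± 0.10) were among the lowest. CDKN1A rose to 88.8 ± 4.7 CPM, a log2 fold change of 0.79 ± 0.04, and TOP1 had one of 0.15 ± 0.04 (adjusted p = 0.00463). Of the 4677 genes called, 2518 were higher and 2159 lower.

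Among the lists, 12 of 29 p53 targets rose and 1 fell (camera adjusted p = 0.000468, adjusted p = 0.0304 with an estimated correlation), and the numbers were the same adjusted over the list alone. Of 16 proneural genes 8 fell (9 adjusted over the list alone, camera adjusted p = 6.24e-08, adjusted p = 0.00179 with an estimated correlation), with SOX2, a stem cell factor, at -0.37. Of 23 inflammatory and secretory genes 12 rose and 5 fell (12 and 6 adjusted over the list alone), LIF among the latter at -0.73 (camera adjusted p = 7.96e-05, adjusted p = 0.0404 with an estimated correlation). By either adjustment, hypoxia genes were lower in 15 of 24 and higher in 1 (camera adjusted p = 1.48e-09, adjusted p = 0.133 with an estimated correlation), and SREBP2 targets lower in 13 of 25 and higher in 2 (camera adjusted p = 0.000499, adjusted p = 0.274 with an estimated correlation). Of the 26 integrated stress genes 14 rose and 4 fell, by either adjustment, with SESN2 at 0.98 and the pseudokinase gene TRIB3 at 0.96 (camera adjusted p = 0.000173, adjusted p = 0.223 with an estimated correlation). Antigen presentation genes rose in 9 of 13 (10 adjusted over the list alone, camera adjusted p = 7.15e-06, adjusted p = 0.0523 with an estimated correlation). Summed markers of neurons went from 1115 ± 38 to 747 ± 15 CPM, of epithelium from 428 ± 22 to 560 ± 32 CPM and of endothelium from 8.45 ± 0.37 to 12.3 ± 1.0 CPM (SD, n = 4). A sum gives most weight to the markers with the highest levels and does not show how many of them moved.

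**Figure D2:**
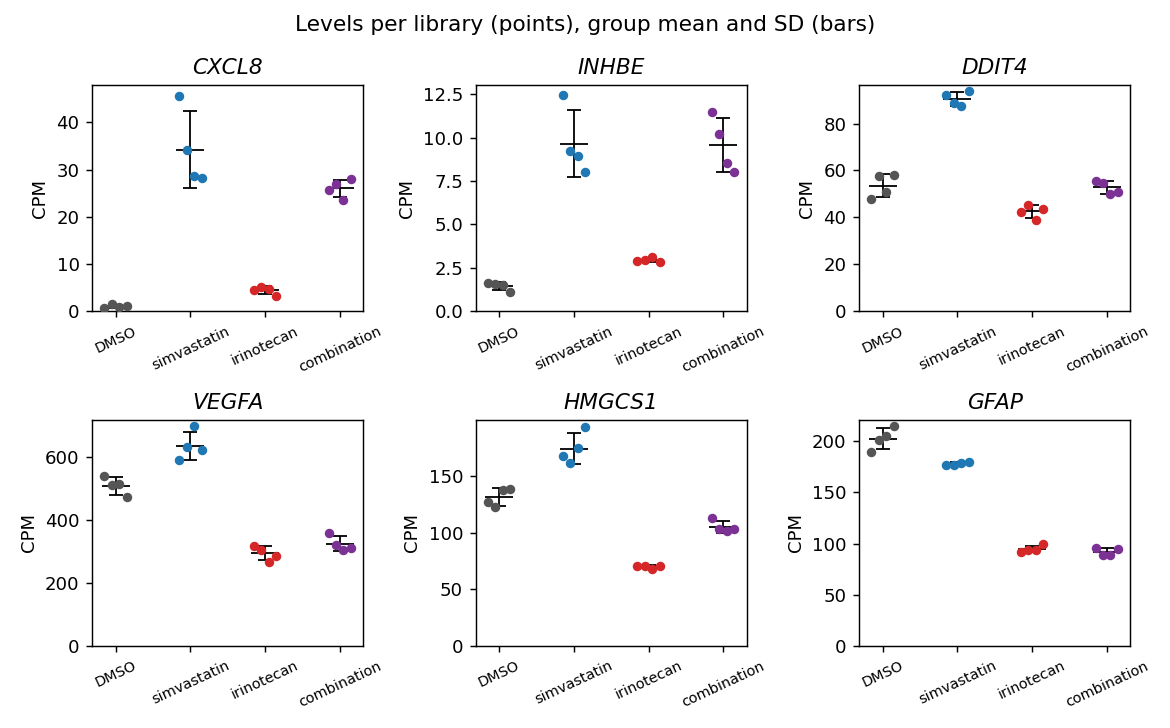
CPM of 6 genes in each library (points), with the group mean and SD (bars, n = 4) on axes that start at 0. CXCL8 and INHBE were high in both groups with simvastatin, VEGFA and HMGCS1 were higher with simvastatin and lower with irinotecan than with DMSO, and GFAP was lower in both groups with irinotecan.

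The combination against irinotecan asked what simvastatin adds to irinotecan. CXCL8 rose from 4.46 ± 0.85 to 26.0 ± 1.9 CPM and INHBE from 2.96 ± 0.11 to 9.56 ± 1.56 CPM (SD, n = 4, adjusted p = 3.05e-07 and 8.5e-10). STC2 (0.91 ± 0.05), CHAC1 (0.85 ± 0.08), the ecto-nucleotidase gene NT5E (0.80 ± 0.08) and the mitochondrial folate enzyme ALDH1L2 (0.90 ± 0.12) rose as well. HMGCS1 rose from 70.0 ± 1.4 to 105 ± 5 CPM, still under DMSO. The keratin gene KRT15 (-0.61 ± 0.08) and UBA7 (-0.51 ± 0.09), which activates the ubiquitin-like protein ISG15, fell. Of the 989 genes called, 740 were higher and 249 lower. With 1 library left out, 126 (without irinotecan replicate 1) to 223 were lower, and the number was 455 without a filter on low counts and 469 with only the compared groups.

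Of 26 integrated stress genes 15 rose and none fell (18 and 0 adjusted over the list alone, camera adjusted p = 2.43e-31, adjusted p = 0.00369 with an estimated correlation), including HERPUD1 (0.63), the chaperone gene HSPA5 (0.39) and XBP1 (0.40), a transcription factor of the unfolded protein response. Inflammatory and secretory genes rose in 9 of 23 and fell in 1 by either adjustment (camera adjusted p = 6.07e-13, adjusted p = 0.00179 with an estimated correlation). Hypoxia genes rose in 11 of 24 (15 adjusted over the list alone, camera adjusted p = 3.17e-18, adjusted p = 0.0447 with an estimated correlation). Immediate early genes rose in 6 of 23 (8 adjusted over the list alone, camera adjusted p = 3.15e-06, adjusted p = 0.0416 with an estimated correlation), with IER3, an early response gene, at 0.51 and DUSP5, a phosphatase for ERK, at 0.37. SREBP2 targets rose in 9 of 25 (13 adjusted over the list alone, camera adjusted p = 4.28e-12, adjusted p = 0.0502 with an estimated correlation), with SQLE at 0.40 and INSIG1 at 0.34. Extracellular matrix genes rose in 15 of 31 (16 adjusted over the list alone), with the collagen genes COL4A1 at 0.41 and COL5A1 at 0.26 (camera adjusted p = 3.48e-16, adjusted p = 0.0507 with an estimated correlation). In the G2/M list 10 of 34 genes fell (16 adjusted over the list alone, camera adjusted p = 1.38e-10, adjusted p = 0.0657 with an estimated correlation). Mitochondrially encoded mRNAs had a median of -0.28 with 0 of 13 called (camera adjusted p = 0.00724, adjusted p = 0.557 with an estimated correlation), beside a mitochondrial share of counts of 3.03% against 3.76%.

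**Figure D3:**
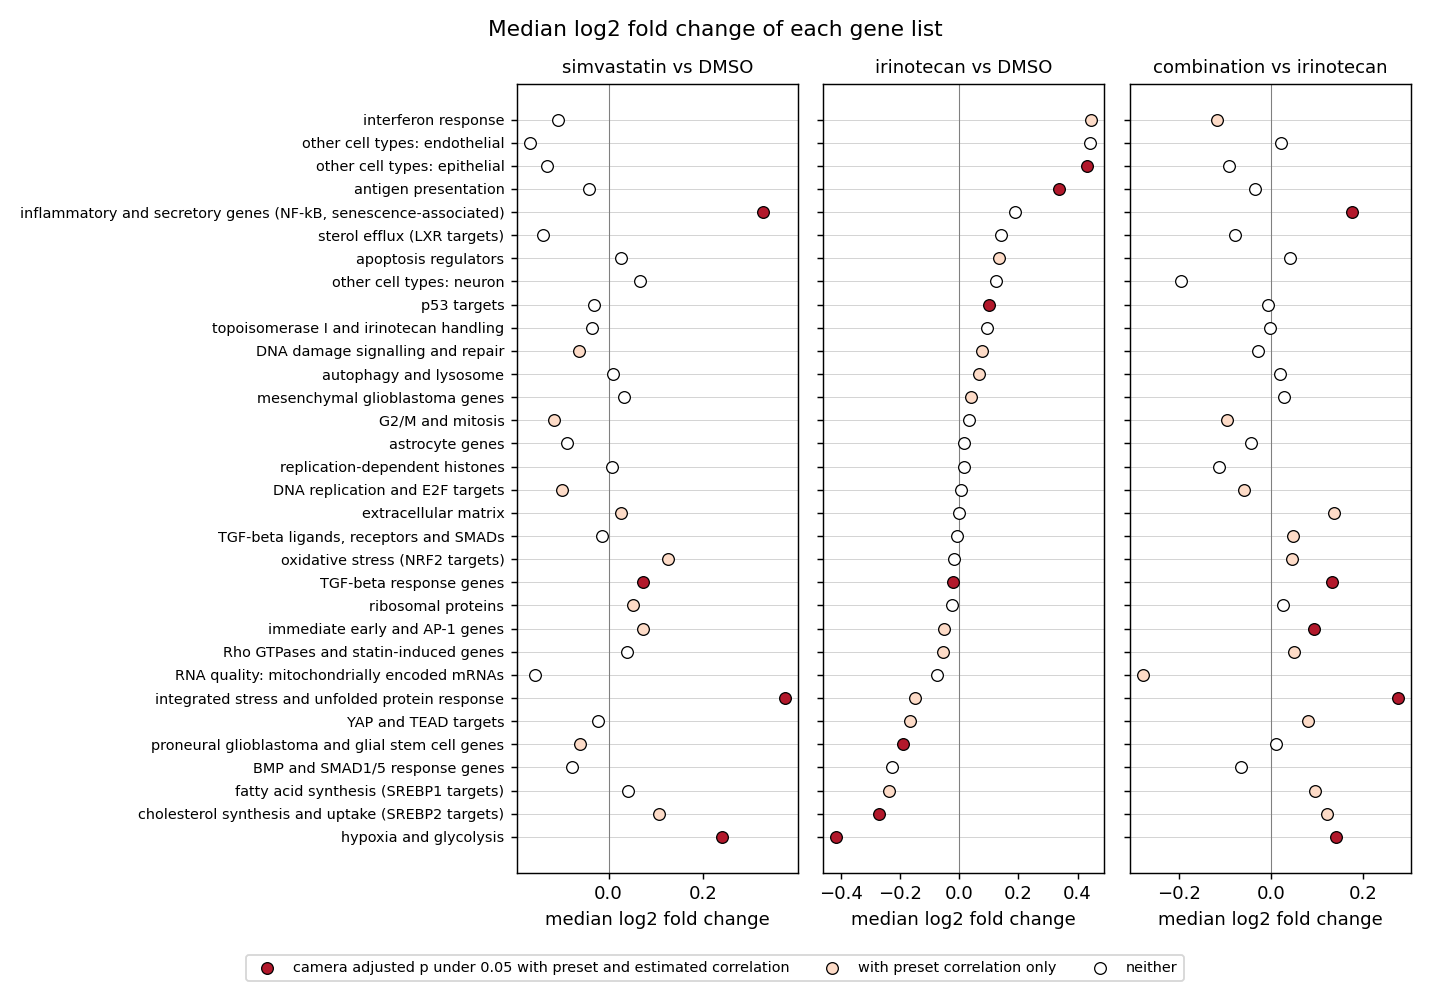
Median log2 fold change of each of the 32 tested gene lists in 3 comparisons (n = 4 libraries per group); fill marks an adjusted p under 0.05 by camera with preset and estimated correlation, with preset correlation only, or with neither. The x axes differ in range. Stress and inflammatory lists were higher with simvastatin, and hypoxia and sterol lists were lower with irinotecan.

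The combination against simvastatin asked what irinotecan adds to simvastatin. The hyaluronan-binding protein gene CEMIP rose by 1.46 ± 0.07, LIPH by 1.68 ± 0.14 and NGFR by 1.29 ± 0.08 on the log2 scale (adjusted p = 4.69e-11, 1.31e-10 and 5.15e-13). LIF fell, with a log2 fold change of -1.24 ± 0.06, and so did the vascular peptide gene APLN (-1.30 ± 0.12) and KCNIP1 (-1.28 ± 0.11). VEGFA fell from 635 ± 45 to 325 ± 24 CPM and GFAP from 178 ± 2 to 92.1 ± 3.9 CPM (SD, n = 4). Of the 4259 genes called, 2306 were higher and 1953 lower. Hypoxia genes fell in 21 of 24 (22 adjusted over the list alone, camera adjusted p = 1.17e-40, adjusted p = 0.0048 with an estimated correlation), SREBP2 targets fell in 17 of 25 and rose in 1 (19 and 2 adjusted over the list alone, camera adjusted p = 1.31e-12, adjusted p = 0.0497 with an estimated correlation), and proneural genes fell in 8 of 16 by either adjustment (camera adjusted p = 4.41e-05, adjusted p = 0.00983 with an estimated correlation). Antigen presentation genes rose in 10 of 13 (11 adjusted over the list alone, camera adjusted p = 6.61e-07, adjusted p = 0.0447 with an estimated correlation). By either adjustment p53 targets rose in 11 of 29 (camera adjusted p = 0.00303, adjusted p = 0.0416 with an estimated correlation) and epithelial markers in 3 of 4 (camera adjusted p = 8.45e-05, adjusted p = 0.0416 with an estimated correlation). The summed epithelial level was 389 ± 15 CPM with simvastatin and 560 ± 32 CPM with the combination (SD, n = 4). Of 26 integrated stress genes 14 fell and 1 rose by either adjustment (camera adjusted p = 5.17e-08, adjusted p = 0.0853 with an estimated correlation). Interferon genes rose in 16 of 29 (17 adjusted over the list alone, camera adjusted p = 1.58e-07, adjusted p = 0.203 with an estimated correlation).

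Most genes that a drug changed alone went the same way when the other drug was present. Of the 999 genes that simvastatin changed alone, 97.6% had the same sign in the combination against irinotecan, and 517 were called there in the same direction and 0 in the opposite one by edgeR (r = 0.27 across all genes, which are not independent replicates). These comparisons share no libraries. Over the 999 genes the slope of the effect with irinotecan on that without it was 0.58, which includes the shrinkage of genes picked for passing a threshold, and over all genes the total least squares slope was 0.91. CHAC1, INHBE, STC2 and LOX were among those called in both. Of the 4015 genes that irinotecan changed, 2747 were called in the same direction when it was added to simvastatin, and 0 in the opposite one (r = 0.64).

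**Figure D4:**
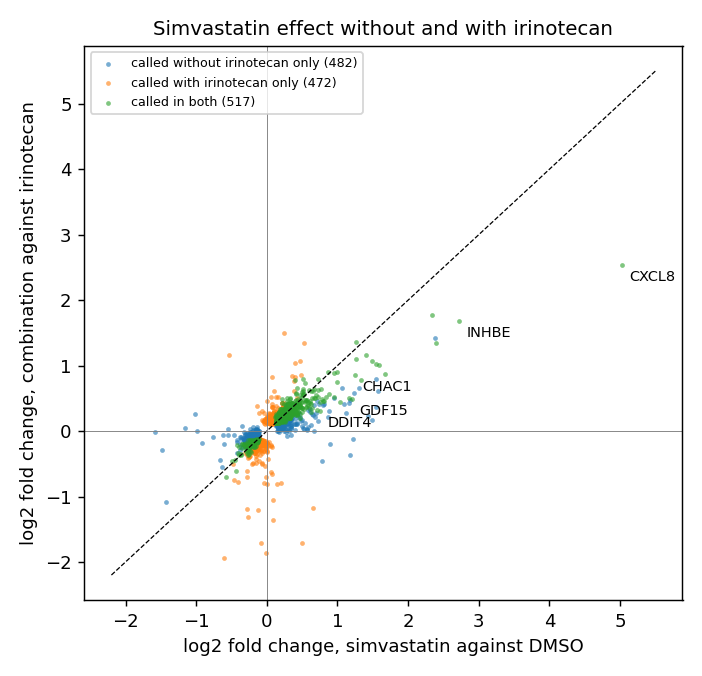
Log2 fold change of simvastatin without irinotecan (x axis) against that with irinotecan (y axis) for genes called in at least 1 of these comparisons (points, n = 4 libraries per group); the dashed line marks equal effects. Of these genes 517 were called in both, 482 only without and 472 only with irinotecan, and CXCL8 lay at 5.03 and 2.54.

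Simvastatin and irinotecan moved some genes together and others apart, in comparisons that share the DMSO libraries. They changed 255 genes in the same direction, 121 higher and 134 lower, where independent calls would give 80.2 and 41.2. With separate DMSO libraries for each drug the mean number was 116. Those separate controls held fewer libraries, so mean numbers from them, here and below, cannot be set against the numbers for independent calls. CXCL8, GDF15, KCNK6 and CDKN1A rose with each drug, and GFAP and PDGFRA, a growth factor receptor gene of proneural tumours, fell with each. In the opposite sense, 160 genes were higher with simvastatin and lower with irinotecan, against 75.8 from independent calls, and their mean number with separate DMSO libraries was 109. Among them were CA9 (0.54 and -1.23), LIF (0.50 and -1.09), VEGFA (0.32 and -0.79) and HMGCS1 (0.41 and -0.91). Another 74 were lower with simvastatin and higher with irinotecan, against 43.6 from independent calls and a mean of 41 with separate DMSO libraries, and the keratin genes KRT15 (-0.43 and 0.38) and KRT8 (-0.23 and 0.56) were among these. Across genes the covariance of the drug effects was 0.0185 (r = 0.25), against 0.0159 (r = 0.50) simulated for unchanged groups that share DMSO libraries, and r had a mean of 0.00529 with separate DMSO libraries.

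In 211 genes the combination differed in the same direction from both single drugs, in comparisons that share its libraries, 137 higher and 74 lower, where independent calls would give 102.5 and 29.2. Another 204 were higher than with irinotecan and lower than with simvastatin, and 57 the reverse, against 86.8 and 34.5 from independent calls. Across genes, which are not independent replicates, the covariance of these effects was 0.0221 (r = 0.29), against 0.0166 (r = 0.51) simulated for unchanged groups that share the combination libraries. Of the 211 genes, 208 were also called against DMSO in the same direction. That comparison uses the same combination libraries by which the genes were picked, so it is no separate support. NOG, a secreted BMP antagonist, was higher by 0.57 ± 0.06 than with irinotecan and by 0.63 ± 0.06 than with simvastatin. HBEGF was higher by 0.56 and 0.84, KCNK6 by 0.79 and 0.73, and GPRC5A, a receptor gene induced by retinoic acid, by 0.52 and 0.58. GDF15 and CDKN1A were higher than with each drug as well, at 34.9 and 88.8 CPM. Without irinotecan replicate 1, combination replicate 1 or combination replicate 3 the number fell to 135, 130 and 122. Without the filter on low counts 98 genes were higher and 150 lower, so which direction prevails depends on that filter. With the replicate number as a block, 327 were higher and 305 lower in the 12 numbered libraries, and 228 and 174 in all 16.

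The title of the series names TGF-β, and its genes moved in different directions with the drugs. Of 31 TGF-β response genes, 4 rose with simvastatin and none fell (6 and 0 adjusted over the list alone, camera adjusted p = 2.7e-05, adjusted p = 0.0321 with an estimated correlation), led by LOX (0.95 ± 0.06), which crosslinks collagen. With irinotecan 6 rose and 12 fell (6 and 13 adjusted over the list alone), and the list tested as lower at a median of -0.02 (camera adjusted p = 0.000285, adjusted p = 0.0494 with an estimated correlation), with PMEPA1, a brake on TGF-β signalling, at -0.70 and CTGF at -0.46. With the combination 9 rose and 6 fell (9 and 8 adjusted over the list alone), COL1A1 among the former at 0.77, and the list did not pass (camera adjusted p = 0.563). Against irinotecan alone, 14 of the 31 rose in the combination (17 higher and 1 lower adjusted over the list alone, camera adjusted p = 2.26e-13, adjusted p = 0.00179 with an estimated correlation), and against simvastatin alone 6 rose and 10 fell by either adjustment, at a median of 0.01 and a mean of -0.08 (camera adjusted p = 0.0715).

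Ligands, receptors and SMADs of the TGF-β family did not pass camera with simvastatin, irinotecan or the combination against DMSO (adjusted p = 0.745, 0.644 and 0.108, n = 36 genes). Fry, which tests a list against no change, called it higher in the combination against DMSO (adjusted p = 0.00309), and against irinotecan it passed camera (adjusted p = 0.0477, adjusted p = 0.309 with an estimated correlation). In the combination 9 of them rose and 5 fell (9 and 6 adjusted over the list alone), among them NOG (1.04 ± 0.06), the activin antagonist FST (1.53 ± 0.16), the ligand BMP4 (1.01 ± 0.11) and GDF11 (0.58 ± 0.05). TGFB1 and TGFBR1 were not called in any comparison. TGFB2 was called in the combination against DMSO alone (-0.21, adjusted p = 0.0235), a call that ended with library sizes alone and without DMSO replicate 3 or 4 or combination replicate 1, 2 or 4, at adjusted p of up to 0.0936 over all alternatives. TGFBR2 rose in the combination (0.26) and SMAD7, the inhibitory SMAD, rose there from 0.437 ± 0.214 to 1.13 ± 0.04 CPM (adjusted p = 0.000989). SMAD3 had log2 fold changes of -0.07 with simvastatin (adjusted p = 0.311), 0.13 with irinotecan (adjusted p = 0.00946) and 0.06 with the combination (adjusted p = 0.234).

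The interaction asked whether the combination departs from the sum of the single-drug log2 effects. It called 2 genes, both below the sum. CXCL8 reached 26.0 CPM in the combination against 34.2 CPM with simvastatin alone, a departure of -2.48 ± 0.33 (SE, n = 4, adjusted p = 0.037). DDIT4 was at 53.6 ± 5.0 CPM with DMSO, 90.5 ± 2.8 with simvastatin, 42.6 ± 2.8 with irinotecan and 52.8 ± 2.7 with the combination (SD), a departure of -0.45 ± 0.08 (ENSG00000168209, chromosome 10, 72273920 to 72276036, adjusted p = 0.037). No gene lay above the sum at the threshold in edgeR, while 1000 genes had an unadjusted p under 0.05 and DESeq2 called 4, of which 1 lay above. Some alternatives in edgeR did call genes above the sum, 4 of 9 without simvastatin replicate 3 among them. With the replicate number as a block, 190 genes were called in the 12 numbered libraries, 93 of them above the sum. In all 16 libraries the block gave 6 genes, 1 of them above. Of the 8 lists past camera, YAP and TEAD targets lay above the sum with a median of 0.13 (camera adjusted p = 2.19e-07, adjusted p = 0.0453 with an estimated correlation), with CTGF at 0.24 and 0 of 23 genes called (2 higher adjusted over the list alone). Both calls were lost without DMSO replicate 2 or 4, simvastatin replicate 1, irinotecan replicate 1 or 4 or any combination replicate, with adjusted p of 0.053 to 0.178 for CXCL8 and for DDIT4. CXCL8 was also lost without DMSO replicate 3 (adjusted p = 0.122) or irinotecan replicate 2 (0.128), and DDIT4 without simvastatin replicate 4 (0.104) or irinotecan replicate 3 (0.108), so that 0 to 9 genes were called with 1 library left out.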

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

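The test of CXCL8 and DDIT4 on the linear scale was chosen only after the interaction had been seen. CXCL8 and DDIT4 stood out because the effect of simvastatin differed with and without irinotecan: the interaction was -2.48 ± 0.33 for CXCL8 and -0.445 ± 0.0791 for DDIT4 (SE, adjusted p = 0.037 for each). If that came only from the log2 scale, CPM values would add up. CXCL8 was at 26.0 CPM where the single-drug changes add up to 37.6 CPM, a gap of -11.6 CPM (SE 4.2). Most of this error came from the spread of the simvastatin libraries alone, so the gap does not rule out that CPM changes add up for CXCL8. For DDIT4 the gap was -26.7 CPM (SE 3.45), but the added changes (79.5 CPM) lay above the multiplied ones (71.9 CPM), so a gene below the second is below the first by construction and the test was not used. Chance stays open for the count of 2 genes, and regroupings of the libraries could not decide on it. Of 100 regroupings 6 called as many, the real one included, and the highest other number was 800. In 3 of them, traded labels put the simvastatin effect itself into the interaction. A less than additive response of these genes may underlie the values, but neither its source nor its presence at other doses was tested.

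For 8 gene lists camera found a simvastatin effect that differed with irinotecan. Median interactions were above 0 for fatty acid synthesis (0.0811, adjusted p = 0.00111), TGF-β ligands, receptors and SMADs (0.0717, adjusted p = 0.00775), extracellular matrix (0.0962, adjusted p = 6.77e-08), YAP and TEAD targets (0.128, adjusted p = 2.19e-07) and immediate early genes (0.0470, adjusted p = 0.0309). TGF-β response genes had a median of 0.0471 (adjusted p = 0.00155) but a mean of -0.04. Medians were below 0 for inflammatory and secretory genes (-0.0474, adjusted p = 0.00111) and for the integrated stress and unfolded protein response (-0.0893, adjusted p = 3.34e-06). With an estimated correlation the YAP and TEAD list kept its call (adjusted p = 0.0453), and the others did not, with adjusted p of 0.258 for fatty acid synthesis, 0.193 for TGF-β ligands, 0.0657 for TGF-β response genes, 0.179 for matrix, 0.0602 for inflammatory genes, 0.158 for integrated stress and 0.258 for immediate early genes. Chance stays open for the number of lists: 42 of 100 regroupings gave 8 or more, and the highest other number was 17. Regroupings that trade labels unevenly carry part of the simvastatin effect, so this share does not decide on chance.

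Of 92 groups of 4 values tested, 4 held a library far from the other 3, and chance gives about 1 in 20. TGFBR1 was at 69.45 CPM in simvastatin replicate 3 against 59.54 to 60.95, and at 56.7 CPM in combination replicate 4 against 59.96 to 60.4. TGFBR2 was at 111.4 CPM in combination replicate 3 against 99.63 to 101.4. HMGCS1 was at 112.7 CPM in combination replicate 4 against 101.6 to 103.4.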

How the results depend on the processing

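Scaling by library sizes alone was the only alternative chosen after the data had been seen. No named gene that was called reversed its direction in any alternative. No called list was called in the opposite direction in an alternative. A list whose direction changed without a call there was not counted as reversed, and fry in either direction gives no direction. Of the named genes called, 79 of 122 with simvastatin, 193 of 234 with irinotecan, 213 of 256 with the combination, 72 of 120 in the combination against irinotecan and 192 of 237 against simvastatin stayed called in every alternative, and 0 of 2 in the interaction. With median-ratio size factors, with only the compared groups and with DESeq2, each number of called genes stayed within 1.5 times its value except the interaction, where DESeq2 called 4. At an adjusted p under 0.01, which is a stricter threshold by construction, the numbers were 558 for simvastatin, 2587 for irinotecan, 3032 for the combination, 529 for the combination against irinotecan, 2681 against simvastatin, 0 for the interaction (edgeR, with 1000 genes at an unadjusted p under 0.05 and 4 in DESeq2 at 0.05) and 67 against both drugs. With an absolute log2 fold change of at least 1 added they were 36, 251, 315, 25, 259, 1 and 6, in the same order, and 1 of the 6 was higher.

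The replicate number as a block gave 2016 genes (12 numbered libraries) and 1586 (16 libraries) for the combination against irinotecan (738 and 519 lower), 190 and 6 for the interaction (93 and 1 of them above the sum), and 632 (327 higher and 305 lower) and 402 (228 and 174) against both drugs; the cause was not tested. Residuals of libraries with the same number correlated at -0.08 to 0.16, with 2 of 18 pairs above 0.1, the bound set for taking numbers as pairs, so the main models held no block. Of these pairs 17 were above 0 (median 0.0559, against -0.0135 for different numbers), and 3 of 12 libraries were closest to their own number in each other group, so a weak link of equal numbers stays open. The 12 numbered libraries without a block gave 513 genes for simvastatin, 707 for the combination against irinotecan, 156 against both drugs and 1 for the interaction, from fewer samples. In the same 12 libraries the block gave 1141, 2016, 632 and 190, in the same order. Without a filter on low counts the interaction called 14 (1 above the sum), and against both drugs 98 genes were higher and 150 lower; the cause was not tested. With 1 library left out the numbers were 664 to 1224 for simvastatin (664 without simvastatin replicate 4), 3393 to 3778 for irinotecan, 3998 to 4615 for the combination, 674 to 996 against irinotecan and 3479 to 4371 against simvastatin. For both drugs they were 122 to 245, with 135 without irinotecan replicate 1, 130 without combination replicate 1 and 122 without combination replicate 3. For the interaction they were 0 to 9: 0 without DMSO replicate 2 or 4, simvastatin replicate 1, irinotecan replicate 1 or 4 or any combination replicate, 1 without DMSO replicate 3, simvastatin replicate 4 or irinotecan replicate 2 or 3, and 9 without simvastatin replicate 3, of which 4 lay above the sum. Fewer samples were fitted there, and no other cause was tested.

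With library sizes alone the median log2 fold change of all genes was at most 0.0749, and this scaling moved the share of higher genes from 51.4% to 77.8% with irinotecan, from 53.8% to 73.4% with the combination, from 54.1% to 73.4% against simvastatin and from 74.8% to 62.9% against irinotecan, so the balance of higher and lower genes depends on the scaling. Separate DMSO libraries for each comparison gave mean overlaps of 116 genes for the drugs, 327 for simvastatin and the combination and 1746 for irinotecan and the combination, against 255, 597 and 2844; each control then held fewer libraries and none was shared, and the cause was not tested. Of 192 list tests 82 passed camera, 26 with an estimated correlation, 108 by fry in 1 direction and 146 by fry in either, which ask different questions of a list. With 200 of 16647 genes changed in the simulation, changes of 0.3 log2 units were recovered in 50% of genes for simvastatin and 44% for the interaction. The cutoff on the unadjusted p becomes stricter when fewer genes are called. The real interaction called 2 genes, so its cutoff was stricter than in the simulation, and the 44% overstates what it could detect.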

Other observations

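The test for leukocyte RNA, and the scaling by library sizes alone, were chosen only after the results had been seen. Some genes of sterol efflux, which liver X receptors induce, rose with irinotecan. Of 9 measured, 4 rose and 2 fell (the same adjusted over the list alone), and the list did not pass camera (adjusted p = 0.26). APOE, a lipid carrier, rose by 1.38 ± 0.16, the transporter gene ABCA1 by 0.61 ± 0.08 and ABCG1 by 1.53 ± 0.38 on the log2 scale (SE). In the combination against DMSO the values were 0.91 for APOE, 0.42 for ABCA1 and 1.95 for ABCG1, all called.

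Immediate early genes fell more often than they rose with irinotecan, 9 against 3 of 23 (9 and 4 adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.214 with an estimated correlation). The growth regulator MYC fell (-0.72 ± 0.05), as did JUN (-0.46 ± 0.04), a subunit of AP-1, and PHLDA1 (-0.48 ± 0.04), while the MAP kinase phosphatase gene DUSP4 rose (0.56 ± 0.04). Lysosome and autophagy genes rose in 11 of 30 (12 adjusted over the list alone, camera adjusted p = 0.0215, adjusted p = 0.284 with an estimated correlation), among them the sialidase gene NEU1 (0.40). The summed level of the neuron markers was 1115 ± 38 CPM with DMSO and 782 ± 16 CPM with irinotecan, that of endothelial markers 8.45 ± 0.37 and 12.3 ± 0.5 CPM (SD, n = 4). Of 7 neuron markers tested, 2 rose and 1 fell by either adjustment, with a median log2 fold change of 0.13 (camera adjusted p = 0.545). The lower sum is therefore not a fall of the neuron markers in general.

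Stress response genes were higher with simvastatin, at a median log2 fold change of 0.372 over 26 genes. After removal of a trend with GC content and gene length the median was 0.359 (bootstrap interval over genes 0.246 to 0.464), but the trend was slight, with an SD of 0.0113 and 66 of 16609 genes moved by over 0.05, too small to account for the rise. Library sizes alone also moved little (0.377, interval 0.243 to 0.482), and since a scaling shifts all genes alike, whose median was -0.0024, it could not raise this list apart from them. The 10 leukocyte markers, of which 2 passed the filter on low counts, differed by 0.0964 CPM (SE 0.251) while the stress genes gained 1121 CPM (SE 128). The markers thus showed no gain beyond the error, but in a cultured cell line none was to be looked for, so this check adds little. A response to loss of mevalonate products may underlie the pattern, a hypothesis that was not tested, and simvastatin was given at 1 dose and 1 time.

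Hypoxia and sterol genes were lower with irinotecan, at medians of -0.415 and -0.271. After removal of the GC and length trend the medians were -0.459 (-0.54 to -0.396) and -0.326 (-0.42 to -0.171). With library sizes alone they were -0.339 (-0.412 to -0.267) and -0.196 (-0.289 to -0.0215), where the median of all genes was 0.0749. The trend had an SD of 0.0332, with 4294 of 16609 genes moved by over 0.05, which is small beside these medians. Its removal could therefore not have brought the lists near 0, and the trend was too small to account for the falls. A scaling shifts all genes alike and could not lower these lists apart from the others, so the values with library sizes alone test nothing further. A lower cell density, with less use of oxygen, could lower the hypoxia list, and cell number was not among the deposited data.

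For each comparison with DMSO or between treatments, the number of genes called was set beside other splits of the same 8 libraries, 35 in all. The real split alone reached its number in every case: 999 for simvastatin (highest other 126), 4015 for irinotecan (0), 4677 for the combination (65), 989 against irinotecan (0) and 4259 against simvastatin (0). A share of 1 of 35 is the lowest that these splits can give, and it was not adjusted over the comparisons. Mixed splits also carry the drug effect into the spread within groups. None of them can tell separate cultures from technical repeats. For genes apart from both drugs, 2 of 100 regroupings gave 211 or more, the real one included, with 393 the highest other. These regroupings mix libraries with and without irinotecan, whose large difference then widens the spread within groups and lowers the numbers called. The share therefore cannot decide on chance for the 211 genes. For the number of lists past camera, the real split alone reached its number with irinotecan (17, 1 of 35 splits, highest other 14) and with the combination (15, 1 of 35, highest other 13), by a small margin. Other splits reached it with simvastatin (13, 4 of 35 splits, highest other 15), in the combination against irinotecan (16, 2 of 35, highest other 16) and against simvastatin (13, 6 of 35, highest other 14). Every other split that reached these 3 numbers traded labels unevenly. Such a split still carries part of the drug effect between its groups, so these shares cannot decide on chance for the 3 numbers of lists. In the interaction, where 6 of 100 regroupings called 2 genes or more, 5 were not the real one. In 3 of those, most libraries with and without simvastatin had traded labels in 1 irinotecan level but not in the other. Of 4 simvastatin labels, 3 stayed true without irinotecan and 0 with it at 800 and 419 genes, and 1 and 4 at 308 genes. Such trades put the simvastatin effect itself into the interaction, so these high numbers are no measure of chance. Regroupings with 3 and 1 true labels called 0. The other 2 regroupings, with 656 and 4 genes, had 3 and 2 true labels, and 2 and 3. The source of their numbers was not tested.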
